A study of Drosophila melanogaster with 2 samples.

How the data were processed

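Chromatin from Drosophila melanogaster embryos at stage 11 was cross-linked with 1.8% formaldehyde and sonicated in 9 cycles, per the labels' protocols. A Yan ChIP sample was made with a guinea pig antibody to Yan, and an input sample was taken from the lysate before immunoprecipitation. The protocol describes amplification of the ChIP DNA by linker-mediated PCR. It also mentions a mock-treated portion of the lysate, which was not analysed here. Each group held 1 sample. The 2 ChIP lanes were runs of that sample and were never treated as replicates.

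The deposited files were 3 lists of aligned reads (ChIP lane 2, ChIP lane 3 and input lane 1), a table of Yan peaks with its BED copy, and a table of negative peaks. Reads were 36 bases long. The aligner and the genome build are not given in the sources used here. Each read line gave a chromosome, a position, a strand, a match descriptor and an alignment score that the authors' aligner assigned, and the score was not used here. Peaks were called by the authors with MACS version 1.4.0 on the pooled reads of both ChIP lanes against the input, per the file headers. The cutoff was a p of 1e-05, the effective genome size was set to 1.2e+08 bp, and the tag shift model gave a d of 200 bp. At most 2 tags per position were kept in the ChIP and 3 in the input, which removed 213572 ChIP tags (9.18%), per the file headers. After that filter the input held 2.96 times as many tags as the ChIP, and the smaller set was scaled up to the larger. The tag counts per peak were deposited as raw whole numbers after this filter. The fold enrichment of each peak is the authors' ratio of tags at the summit to the scaled local expectation. The significance score deposited with each peak is the authors' 10 times the negative log10 of the Poisson p. The false discovery rate was deposited as a percent and came from exchanging ChIP and input, per the file headers. The negative peaks are the regions called in that exchange. All 3311 peaks of the BED copy had the positions and scores of the table.

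Counting reads beyond 2 per position and strand in the ChIP gave 213572, and reads beyond 3 in the input gave 15005, the numbers removed in the header. Reads were counted in a region by their 5′ end. Ratios of ChIP to input were taken per mapped read with 0.5 read added to both, scaled by all mapped reads or, where stated, by the reads on the 6 main arms (2L, 2R, 3L, 3R, 4 and X). Shares carry exact Clopper-Pearson intervals at 95%, single-region ratios carry exact conditional binomial intervals, and medians over peaks carry order-statistic intervals. Intervals of read ratios and read shares cover counting error only, and PCR reads without molecular identifiers are not independent molecules. Those of medians, motif shares and cluster shares treat peaks or summits as independent draws, although many peaks lay in clusters. None covers variation between samples. With 1 sample per group no test between ChIP and input as conditions was possible, and no p-value is given across peaks.

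No genome sequence of the files' build was used. The bases under the reads were rebuilt from each read and its match descriptor, which gave 82.1 Mb of the 6 arms (68.3% of the positions up to the last read). Over all sequences in the files, on the arms and elsewhere, 2 or more reads gave a base at 58.7 Mb, and 0 positions disagreed. The descriptors give the reference base at each mismatch, so this checks the rebuilding only. Motifs were searched on both strands within 100 bp of each summit where at least 90% of the bases were known, which held for 2784 summits on the arms (84.8%). Background windows were windows shifted 2 kb to either side of the summits, 1000 random placements on the same arm, and 100 sets of random windows matched on arm and on GC content in 2% bins. The rule of 90% known bases was applied again after the shift. It left 2261 shifted windows from both sides of the 3283 summits on the arms. Known bases depend on the reads, so the shifted windows are a selected background. The windows matched on GC were chosen after seeing the data. A cluster was 3 or more summits with successive gaps of at most 5 kb. Random placements fell on known bases only. The motifs CCGGAA, its reversed form AAGGCC, CAGGTA, GAGAGAG, CAYRTG, TCAAGTG, SCTTTGWW and YGTGRGAA, the cluster definition and most alternatives were fixed before the data were examined. The motifs GGAAGT, CACACA and GAGAGA and the search over 2080 words of 6 bases were added afterwards.

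The rule for named genes, also fixed beforehand, named the genes at the 10 peaks of highest fold enrichment, the genes with most peaks, and members of 19 gene lists. The gene table at hand is of Release 6, where genes on 2R reach 25.3 Mb, while the reads on 2R ended at 21.1 Mb. The builds therefore differ, coordinates were not converted, and peaks were not assigned to genes. The planned shares of peaks at transcription start sites and of genes bound in each list were left out for that reason. Regions are named by position in the build of the deposited files. The 10 peaks of highest fold follow the rule, and the peaks named on the arms and the named clusters were chosen after their values were seen.

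Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The steps were tested on simulated data. Rebuilding returned 0 wrong bases of 108000, the motif search found 301 of 301 planted windows, 96.4% of the ratio intervals held the true ratio and 95.1% of the median intervals held the true median. Alternatives included other peak thresholds, 1 read per position and strand, each lane by itself, other scalings, other cluster gaps, and other motif forms and windows.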

Results

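Binding of Yan, an ETS-domain transcriptional repressor that acts downstream of receptor tyrosine kinase signalling, was mapped by chromatin immunoprecipitation and sequencing in whole stage 11 Drosophila embryos, with input DNA as the reference. Each group consisted of 1 sample, so there were no replicates. The Yan ChIP was sequenced in 2 lanes with 444123 mapped reads in lane 2 and 1881412 in lane 3, and the input lane held 6271848. On the 6 main arms, 235211 reads remained for lane 2, 1831440 for lane 3 and 6084376 for the input. Lane 3 thus gave 88.6% of the ChIP reads on the arms. The remaining lane 2 reads lay almost entirely on Uextra, a collection of unplaced sequence, which took 46.1% of lane 2 against 0.340% of lane 3 and 0.329% of the input. Reads on the arms had a GC content of 53.6% in lane 2, 49.7% in lane 3 and 49.8% in the input.

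The first question was where Yan associated with the genome. The authors listed 3311 Yan peaks with a median length of 777 bp, of which 3283 lay on the main arms. Their fold enrichment was low in most cases, with a median of 1.55 and an upper quartile of 2.06. The highest on the arms was the peak on X from 2211257 to 2212208, at 14.44-fold, with 144 ChIP reads against 40 input reads. It was followed by 3R from 21340747 to 21341823 at 10.48-fold, 3L from 14183751 to 14184535 at 10.25-fold and 2L from 19574610 to 19577041 at 9.51-fold. In that order, from X to 2L, the authors' false discovery rates were 4%, 14.55%, 11.11% and 5%. The peak on 2L was broad and rested on 709 ChIP and 244 input reads, a ratio of 8.55 (7.39 to 9.94) when scaled by the reads on the arms. Several of the strongest peaks were neighbours. On 3R, the peak from 19125376 to 19127625 (9.02-fold) lay near those from 19139683 to 19140625 (8.46-fold) and from 19140738 to 19141648 (9.30-fold). On 3L, the peaks from 16465860 to 16467122 (8.62-fold) and from 16468204 to 16469812 (8.42-fold) were adjacent, as were those on 2R from 9452926 to 9456511 (8.41-fold) and from 9456528 to 9458040 (6.73-fold). Among these neighbours, the authors' false discovery rate was 7.5% for 3R from 19139683, 5.41% for 3R from 19140738 and 14.29% for 2R from 9456528. For the others it was at most 5%.

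All 10 peaks of highest fold in the whole list lay on Uextra, at 19.89-fold to 153.13-fold. In 9 of them lane 2 gave more reads than lane 3. The highest, from 7039237 to 7039876, held 32775 reads of lane 2, 54 of lane 3 and 4 of the input. The exception, from 5223880 to 5224602, held 409 reads of lane 3, 14 of lane 2 and 25 of the input, at 28.34-fold. Of the 17 Uextra peaks, 11 had more lane 2 than lane 3 reads, and these 11 took 45.9% of all lane 2 reads.

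With ChIP and input exchanged, the same caller gave 5224 negative peaks, more than the 3311 Yan peaks. Negative peaks were longer, with a median of 1520 bp, and had a higher median fold of 3.62. Accordingly, the authors' false discovery rate was 100% for 2698 Yan peaks (81.5%) and at most 5% for 31, of which 20 lay on the arms and 11 on Uextra. At a limit of 1% the count was 0. Fold enrichment was at least 5 in 57 Yan peaks, of which 42 lay on the arms, and in 362 negative peaks. The lists overlapped at 84 Yan peaks by at least 1 bp, against a median of 465 and a lowest value of 427 in 100 random placements of the 3283 peaks on the arms. Because the lists were called in opposite directions from the same reads, a low overlap follows from the calling. Yan peaks had a median GC content of 49.7% around the summit and negative peaks one of 60.7%. When the reads in each listed region were scored again with the input scaled down to the ChIP depth, 1198 of the 3311 peaks (36.2%) reached a Poisson p of 1e-05, and 1484 (44.8%) did so by a conditional binomial test, which 2568 of the 5224 negative peaks (49.2%) also passed. Scaled by arm reads, the binomial test was passed by 1696 of the 3283 Yan peaks on the arms (51.7%, 49.9% to 53.4%) and 1819 of the 5157 negative peaks there (35.3%, 34.0% to 36.6%), which turned the order of the shares. That test compares these libraries and not conditions, and it makes no allowance for GC content.

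Read counts gave the size of the enrichment. The median ratio of ChIP to input over the Yan peaks was 2.51 (95% interval 2.46 to 2.56) by all mapped reads, and 2.73 (2.68 to 2.78) on the arms by arm reads. In negative peaks on the arms it was 0.529 (0.525 to 0.534). The Yan peaks on the arms held 8.55% of the ChIP reads there (8.51% to 8.59%) and 3.17% of the input reads (3.16% to 3.19%). Over all chromosomes these shares were 16.4% and 3.09%, and counting 1 read per position and strand brought the ChIP share to 8.28%.

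**Figure D1:**
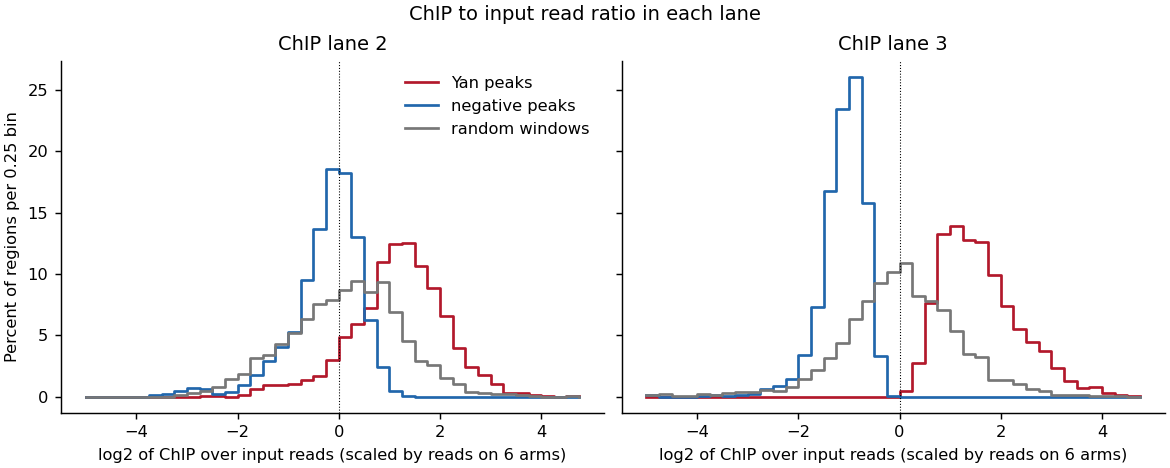
Distribution of the log2 ratio of ChIP to input reads, scaled by the reads on the 6 arms, in lane 2 (left) and lane 3 (right), for 3283 Yan peaks, 5157 negative peaks and as many random windows as Yan peaks; lines give the percent of regions per bin of 0.25. Yan peaks lie to the right of random windows in both lanes, while negative peaks lie to the left of 0 in lane 3 and close to 0 in lane 2 (median ratios 0.485 and 0.916).

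Both lanes were then compared peak by peak. Scaled by arm reads, the median ratio to input over the Yan peaks on the arms was 2.35 in lane 2 and 2.81 in lane 3. Lane 2 exceeded the input in 90.1% of these peaks (89.0% to 91.1%), against 58.5% (56.8% to 60.2%) of random windows of the same lengths. A ratio of at least 2 in each lane by itself was found for 1564 peaks, against 249 of the random windows. The peak on X from 2211257 to 2212208 held 18 reads of lane 2 and 126 of lane 3, and that on 3R from 19125376 to 19127625 held 34 and 321. The peaks on 2R from 942662 to 943261 and on 3L from 8032490 to 8033318, among the 20 of highest fold on the arms, held 0 reads of lane 2. The authors' false discovery rates for them were 25.62% and 20.86%. Across the 3311 peaks, the log2 read densities (RPM) of the lanes had a Spearman correlation of 0.541 (bootstrap interval 0.515 to 0.568) and a Pearson correlation of 0.505. On the arms the Spearman correlation was 0.551 (0.525 to 0.577) in peaks and 0.515 (0.489 to 0.542) in random windows, while lane 3 and the input correlated at 0.678 (0.659 to 0.698) in the same peaks. As log2 ratios to the input, the correlation was 0.226 in peaks and 0.323 in random windows, so the peaks did not exceed random windows clearly by either measure. Both log2 ratios share the same input counts, which can by itself raise their correlation. The comparison of ratios thus does not settle whether the lanes agreed better in peaks. Peaks are not independent replicates, and the peaks were called mainly on lane 3 reads, so its ratio above 1 in all 3283 peaks on the arms is no separate evidence. The lane 2 reads were also in the pool on which peaks were called, against the same input, and the random windows were not matched on GC. The lane 2 share above input and the 1564 peaks are therefore no independent evidence either. In negative peaks the median ratio was 0.485 in lane 3 and 0.916 in lane 2.

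The ratio of ChIP to input also varied with base composition. In 1 kb windows outside both peak lists, the lane 3 ratio was 0.145 at 26% to 28% GC, 1.08 at 44% to 46% and 0.623 at 56% to 58%. In lane 2 it was 0.415, 1.08 and 1.19 at the same GC contents, so the lanes differed at the low and high GC contents and not at 44% to 46%. The windows needed 80% known bases, which depends on the reads themselves, and the first of these bins held 71 windows.

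Peaks were then placed along the chromosomes. The arms 2L, 2R, 3L and 3R carried 28.9 to 32.1 Yan peaks per Mb, while X carried 15.6 (14 to 17.3) and chromosome 4 carried 15.9 (9.84 to 24.3). The density on X was 0.518 times that of the 4 large autosomal arms (0.462 to 0.579). Input reads per kb on X were 0.822 times the autosomal value, and the density of negative peaks on X was 1.09 times the autosomal one (1.02 to 1.17).

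**Figure D2:**
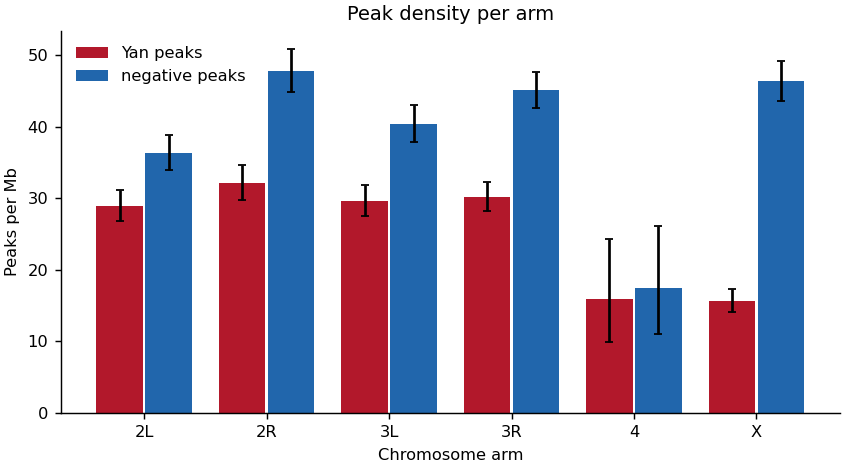
Peaks per Mb on each main arm, with bars for the Yan peaks (red) and the negative peaks (blue) and error bars of the 95% Poisson interval. Yan peaks stand at 15.6 per Mb on X against 28.9 to 32.1 on 2L, 2R, 3L and 3R, and negative peaks at 46.3 on X against 36.3 to 47.8.

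Yan peaks were grouped along the arms, and ratios in clusters are scaled by the reads on the arms. Of the 3283 peaks, 921 (28.1%, 26.5% to 29.6%) lay in 237 clusters of 3 or more summits with gaps of at most 5 kb. Random placements gave a median of 5.39% and at most 7.52%, and 0 of 1000 reached the observed share. The cluster with most peaks lay on 2R from 14553562 to 14576853, where 10 peaks spread over 23.3 kb. Its strongest peak, from 14564635 to 14566406, had a fold of 7.26, and 2 of its peaks had a fold below 1. Clusters of 8 peaks each were found on 3L from 14953463 to 14973049, on 3L from 10837539 to 10855152 and on 2L from 14428805 to 14447049. The cluster on 2R from 9447393 to 9460309 had 6 peaks and the highest ratio of both lanes together among the 20 largest clusters, 7.02 (6.30 to 7.82) over its whole length. Its ratio was 4.04 (3.13 to 5.16) in lane 2 and 7.40 (6.64 to 8.26) in lane 3, so this rank rests on lane 3. On 3R from 19118633 to 19127625, 6 peaks gave a ratio of 4.65 (4.19 to 5.18), with 4.58 (3.67 to 5.67) in lane 2. Clusters held 5 or more peaks in 58 cases, and the median span was 7.27 kb.

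Peaks in clusters were somewhat higher than others, with a median ratio, scaled by arm reads like those that follow, of 3.02 (2.91 to 3.16) against 2.63 (2.56 to 2.70). The stretches between the peaks of a cluster, leaving out 500 bp next to each peak, gave lane 3 ratios of 1.23 (1.2 to 1.26), the 5 kb flanks of clusters 1.1 (1.09 to 1.12) and random 5 kb windows 0.994 (0.990 to 0.998). In lane 2 these ratios were 1.09 (1.03 to 1.16), 1.06 (1.03 to 1.09) and 1.02 (1.01 to 1.03). The 5 kb flanks of peaks outside clusters gave 1.093 (1.089 to 1.096) in lane 3 and 1.055 (1.046 to 1.064) in lane 2. The raised flanks were thus not particular to clusters. Of the 20 arm peaks at a false discovery rate of at most 5%, 11 lay in a cluster of the full list (31.5% to 76.9% by Clopper-Pearson), as did 17 of the 42 of at least 5-fold (40.5%, 25.6% to 56.7%). Neither of these smaller sets formed a cluster by itself, and random placements of as few peaks formed 0 clusters too. Merging peaks less than 500 bp apart left 18.8% in clusters against a random median of 4.61%.

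**Figure D3:**
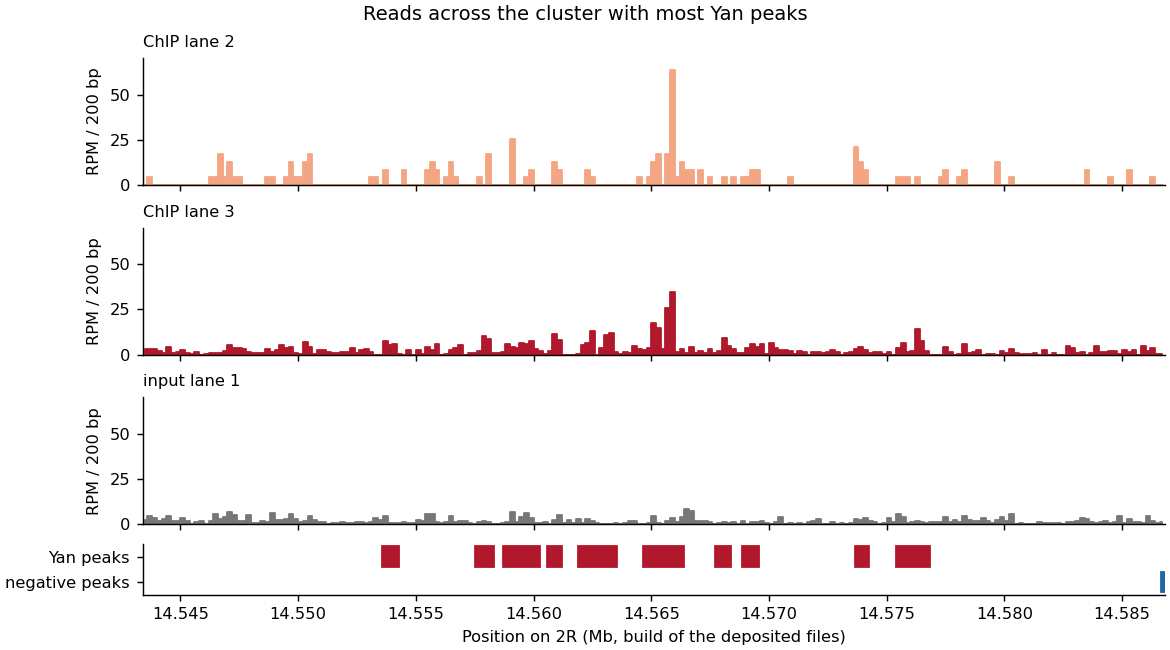
Read density (RPM of the reads on the arms) in 200 bp bins across the cluster on 2R from 14553562 to 14576853 with 10 kb to either side, for ChIP lane 2, ChIP lane 3 and input on the same vertical scale, with the listed peaks below. The 10 Yan peaks are red, the highest at 14564635 to 14566406, and the negative peak at the right edge is blue.

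The sequence at the summits was examined for the ETS core, the element bound by the protein family to which Yan belongs. CCGGAA lay within 100 bp of 10.3% of 2784 summits (9.17% to 11.5%), against 7.25% of windows shifted by 2 kb (6.22% to 8.40%). Random placements gave a median of 8.73%, with 4 of 1000 at or above the observed share, and windows matched on GC gave a median of 8.44% and at most 10.2%. The reversed control AAGGCC was found at 6.79% of summits (5.88% to 7.79%) and in 7.21% of shifted windows. CCGGAA thus had a ratio of 1.42 to shifted windows (1.16 to 1.73), and differences from other ETS forms were not tested. ACCGGAAGT with at most 1 mismatch lay at 6.79% of summits and in 2.96% of shifted windows, a ratio of 2.29 (1.73 to 3.07). GGAAGT lay at 13.9% and in 8.54%, a ratio of 1.63 (1.37 to 1.95). Both intervals overlapped that of CCGGAA, that of ACCGGAAGT only at its edge. The short core GGAA lay at 81.8% and in 79.8%, a ratio of 1.02 (0.963 to 1.09). Matches to CCGGAA were densest right at the summit, with 0.651 per kb in the 100 bp before it, against a median of 0.343 per kb (0.238 to 0.418) over the 30 bins of 100 bp more than 500 bp away. With windows of 250 bp to either side, the share was 17.6% against 18.9% in shifted windows, a ratio of 0.928 (0.787 to 1.09). The known-base rule left 1912 summits and 1389 shifted windows at that width. Width and set thus changed together, and the ratio does not show where the excess ends. The summits of negative peaks held CCGGAA at 12.4% (11.5% to 13.4%) and AAGGCC at 11.2%.

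Motifs at the summits varied with peak height. CCGGAA was present at 8.78%, 8.25%, 9.16% and 14.7% of summits in rising quartiles of the authors' fold, the last with an interval of 12.2% to 17.5%. Shifted windows of the top quartile gave 7.50%. GGAAGT rose from 9.08% (7.03% to 11.5%) in the lowest quartile to 23.4% (20.4% to 26.7%) in the highest, against 8.48% in the shifted windows of the latter, and AAGGCC stood at 6.73% and 6.37%. Some other motifs rose from the lowest to the highest quartile too. CAGGTA went from 7.03% to 11.4%, GAGAGAG from 8.93% to 13% and CACACA from 24.7% to 33.0%. The intervals of these quartiles overlapped for CAGGTA and GAGAGAG. Shifted windows rose as well, from 3.88% to 6.31% for CAGGTA, 3.57% to 4.93% for GAGAGAG and 13.95% to 19.5% for CACACA. No interval was computed for the shifted windows by quartile. For CAGGTA they stood at 6.53% in quartile 3 and 6.31% in the highest, while summits went from 7.41% to 11.4%. For GAGAGAG they were lowest in quartile 3, at 2.11%. Whether the rise of these motifs was particular to the summits was thus not settled. SCTTTGWW did not rise, at 6.15% and 5.82%. Among peaks of at least 3-fold, 32.2% of 214 summits (26.0% to 39.0%) held GGAAGT.

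**Figure D4:**
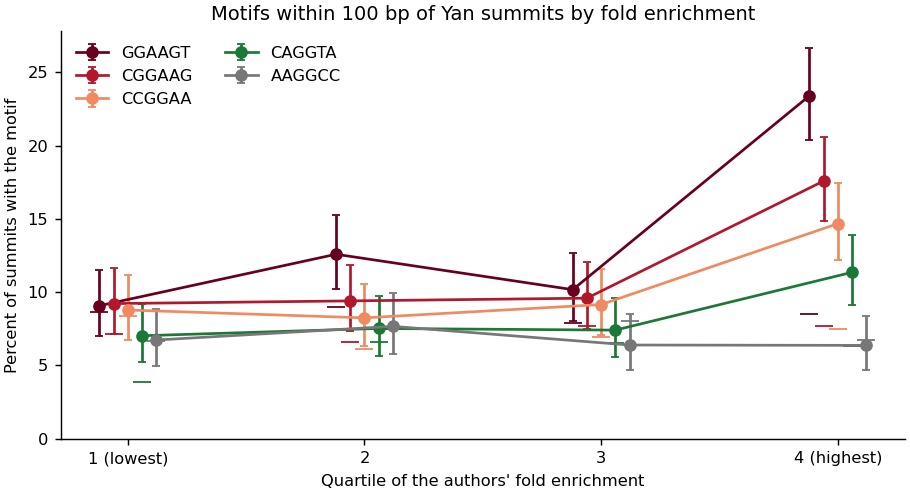
Percent of Yan summits with each motif within 100 bp, by quartile of the authors' fold enrichment, with points and 95% Clopper-Pearson error bars and short horizontal marks for the same windows shifted by 2 kb. GGAAGT reaches 23.4%, CGGAAG 17.6% and CCGGAA 14.7% in the top quartile, while the reversed control AAGGCC stays at 6.37%.

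Other motifs fixed beforehand were compared in the same windows. GAGAGAG, the element of GAGA factor, lay at 10.8% of summits (9.65% to 12%) and in 3.49% of shifted windows, and windows matched on GC gave at most 3.63%. CAGGTA, bound by the early embryonic activator Zelda, lay at 8.37% (7.37% to 9.46%) against 5.75% (4.83% to 6.79%), and at 11.4% in the top quartile of fold. The E-box CAYRTG, of the class bound by Twist, was found at 19.8% (18.4% to 21.4%) against 15.6% (14.1% to 17.1%). Shares for TCAAGTG, the Tinman element, were 5.57% (4.74% to 6.49%) and 4.20% (3.41% to 5.11%). For the TCF element SCTTTGWW they were 6.57% and 5.97%, and for the Su(H) element YGTGRGAA 2.98% and 2.39%, and the intervals of summits and shifted windows overlapped for all 3 elements. Against windows matched on GC, the Tinman element (at most 5.24%) and the Su(H) element (at most 2.69%) exceeded all 100 sets and the TCF element (at most 6.68%) was reached by 1, and all 3 exceeded the 1000 random placements. At negative summits GAGAGAG was found at 1.09%, CAGGTA at 5.53% and CAYRTG at 14.2%.

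**Figure D5:**
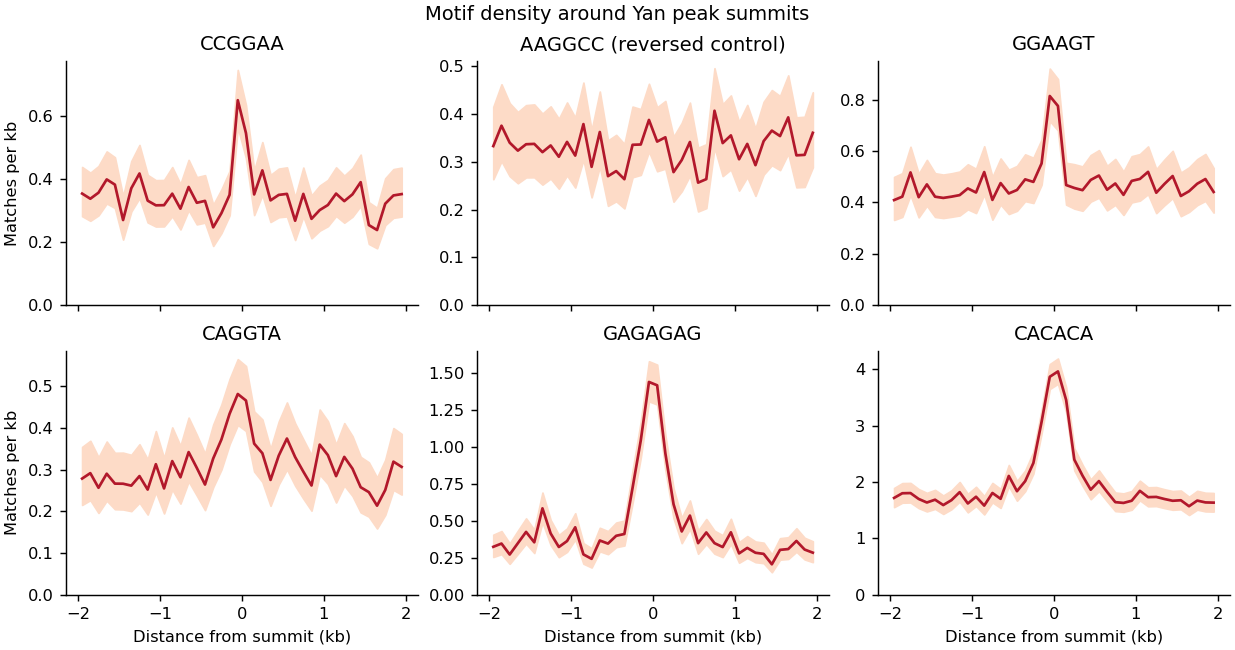
Motif matches per kb of known sequence in 100 bp bins from 2 kb before to 2 kb after the Yan summits, for 6 motifs, with shading for the 95% Poisson interval. CCGGAA reaches 0.651 per kb, GGAAGT 0.814 and GAGAGAG 1.44 in the bin before the summit, and AAGGCC stays near its level elsewhere, at 0.388.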

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

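In this part, the tests on the Uextra peaks were chosen after their result was seen, as were the thinning scaled by arm reads, its comparison with unthinned values and the alternative settings of the GC tiles. A signal outside the main measurement was found in ChIP lane 2, where 46.1% of the reads lay on Uextra against 0.329% of the input reads.

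The strongest peaks of the list lie on Uextra. If chromatin bound by Yan gave these reads, lane 3 of the same sample should hold them too, but over the 10 peaks of highest fold the median ratio of lane 3 to lane 2 read densities (RPM) was 0.000393 (0.000305 to 0.00249), which argues against it for the 9 with a ratio below 0.1. A candidate explanation is DNA of another source in lane 2: a median of 97.8% of the lane 2 reads in the 10 peaks mismatched the assembly, against 14.3% on the arms, and its source was not identified. Binding stays open at the other peak, Uextra from 5223880 to 5224602, with a ratio of 6.67, and at the 6 Uextra peaks without a majority of lane 2 reads, it included, the ratio was 0.973 to 16.1.

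More negative than Yan peaks were listed, and the greater depth of the input was tested by thinning it to the ChIP depth and scoring the listed regions with a binomial test. The ratio of negative to Yan peaks passing rose from 1.73 to 2.0 (1.92 to 2.09) scaled by all reads. By arm reads it rose from 1.07 to 1.13 (1.08 to 1.2). By the rule fixed beforehand, the value by all reads went against depth among these regions, and that by arm reads was undecided. Only regions listed at full depth were scored and the caller itself was not rerun, so depth stays open as a cause of the longer list. Lower recovery of GC-rich DNA in ChIP lane 3 may contribute: from the GC of 1 kb windows alone, a median lane 3 ratio of 0.877 was predicted at negative peaks, where 0.485 was observed. In lane 2 the observed median there was 0.916, and 1 kb windows at 56% to 58% GC gave 1.19. In 200 bp tiles the lane 2 ratio went from 1.41 at 46% to 48% GC to 1.11 at 56% to 58%. Scored against the ratio expected from the GC of 200 bp tiles, the ratio of negative to Yan peaks was 0.632 (0.568 to 0.703), against 1.08 without GC on the same regions, but the 3 other settings of known bases and curve scaling raised it, to 1.43 to 1.65. The tiles behind the expected ratio included those in the listed peaks, so it was partly drawn from the regions scored. GC therefore stays open, and no biological explanation was tested.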

How the results depend on the processing

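The alternatives chosen after seeing the data were those scaled by arm reads or limited to the arms, the rescored and merged peaks, the log2 ratio to input, the GC-matched windows, the strict peaks in clusters of all peaks, GGAAGT and the summits without repeats. Of 48 alternatives, 8 stayed within the error of the main value (within 1.5 times for counts), 39 moved beyond it and 1 changed sign. Many of them, such as stricter thresholds, other cluster gaps and other motifs or windows, measure another quantity. The tally is therefore no measure of robustness. Where a cause is not plain from the setting, the cause was not tested.

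The number of Yan peaks fell to 31 and 0 at false discovery rates of 5% and 1%, 57 at 5-fold, 651 with 2-fold in each lane (1564 by arm reads), 1198 by the rescored Poisson p and 1484 by the binomial p (1696 by arm reads). Negative peaks of at least 5-fold numbered 362, those passing the binomial p 2568 (1819 by arm reads), and 23 peaks overlapped by 50% of the shorter. The median ratio of 2.51 became 2.68 with 1 read per position and strand, 2.96 by bins without a peak, 1.28 in lane 2, 2.83 in lane 3, 9.49 at a false discovery rate of 5% and 2.73 by arm reads. The lane correlation was -0.316 over the 31 peaks at 5% (interval -0.555 to 0.198), which include the 11 on Uextra, and 0.226 as log2 ratios. Reads in peaks were 8.28% with 1 read per position and strand, 49.8% in lane 2, 8.53% in lane 3 and 8.55% on the arms. The clustered share was 7.40% with gaps of 2 kb, 45.9% with 10 kb, 18.8% after merging, and 0 when clusters were formed from peaks at a false discovery rate of 5% or of 5-fold alone, as in random placements of so few peaks. Of these peaks, 55% and 40.5% lay in clusters of all peaks. It was 5.20 times the random median, and 3.85 times that of GC-matched windows among summits with known bases. The ETS share was 6.17% within 50 bp, 17.6% within 250 bp, 15.8% at a false discovery rate of 5% (19 summits) and 25% at 5-fold (40 summits). It was 11.5% for CGGAAG, 81.8% for GGAA, 6.79% for ACCGGAAGT and 13.9% for GGAAGT.

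The alternatives on start sites, gene lists and control lists were not run, since peaks were not assigned to genes. No paired analysis was possible because each group had 1 sample. The lane 2 depth, with a median of 4 reads per peak on the arms, limits what single peaks show in that lane.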

Other observations

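A search over all 2080 words of 6 bases (with their reverse complements), made after the data were seen, ranked the sequence at the summits against windows matched on GC. AGAGAG (3.62 times) and GAGAGA (3.51 times) led over all summits, followed by AGATAC (2.30 times), ACACAC (2.18 times) and CACACA (2.12 times). CCGGAA ranked 384 at 1.16 times, GGAAGT 43 at 1.56 times and CAGGTA 27 at 1.68 times. In the top quartile of fold, GGAAGT ranked 4 at 2.83 times, AGGTAG 5 at 2.76 times, CAGGTA 8 at 2.49 times and CGGAAG 10 at 2.43 times, while CCGGAA ranked 56 at 1.70 times and AAGGCC ranked 1705 at 0.745 times. Ranks describe these libraries and were not tested.

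Repeats of CA and GA stood at many summits, with CACACA at 29.3% against 16.1% of shifted windows and 7.35% of negative summits. A possible explanation is that such repeats raise the ratio of ChIP to input anywhere. Outside both lists, 1 kb windows with CACACA had 1.04 times the lane 3 ratio of GC-matched windows without it (1.03 to 1.05), a small difference, but this used 23854 of 36930 windows and left out those that were listed for their ratio, so it does not exclude the explanation. Over all windows, a test chosen after the result was seen, the value of the same form was 1.13 (1.11 to 1.14), and by medians it was 1.05 (1.03 to 1.07) outside the lists and 1.11 (1.09 to 1.13) over all, but all windows hold the peaks themselves, so it does not bear on repeats elsewhere. Binding of another protein at these repeats was not tested, and at summits without either repeat CCGGAA was found at 10.9% against 7.36% of shifted windows.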
